A study of Mus musculus with 26 samples.

How the data were processed

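Polyadenylated RNA libraries from 20 mouse livers and 4C libraries from 6 mouse livers were examined. The Bmal1 experiment had 12 RNA-seq libraries, 3 each of control and knockout livers at CT0 and CT12. The Nr1d1 experiment had 8 RNA-seq libraries, 2 each of the same 4 groups. The 4C libraries came from wild-type livers, 3 at CT6 and 3 at CT18. Groups were taken from the sample titles.

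The RNA-seq values were deposited as RPKM (reads per kilobase of transcript, scaled to the depth of the library), 1 value per Ensembl transcript and library. The 4C values were deposited as a raw count of reads per restriction fragment of chromosome 5, with fragments that had no read left out. TopHat2, Bowtie and bedtools 2.19.1 were used with the mouse build mm9, per the submitters' processing notes, which do not name Bowtie for replicate 2 of the Nr1d1 experiment. The role of each tool, the annotation release, the read filters, the strand setting and the reads counted as the depth are not given in the sources used here.

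The RNA-seq tables were joined on the transcript identifier, and 46585 transcripts present in every library were used. They carried 22322 gene symbols, and each symbol was represented by the transcript with the highest mean log2 value. Of the 374 genes in the fixed lists, 366 matched a symbol. To recover the reads behind RPKM values, the relative depth of each library was taken from the commonest ratio between libraries among transcripts with low values. For each transcript, a unit was then sought that made its values whole reads in every library. The reads of a transcript are therefore known only up to a factor common to all libraries. Whole reads, within a tolerance of 0.05, were found in all libraries for 18192 of 19183 gene transcripts above 0, which is 94.8%. Transcripts with very many reads in any library could not be resolved. The most abundant genes therefore have no recovered reads and are absent from the edgeR fits on recovered reads. Summed over the resolved gene transcripts, the recovered reads were 8.55 M to 14.22 M (M, in units of 1e6) in the Bmal1 libraries. In the Nr1d1 libraries they were 26.67 M to 48.12 M. These sums leave out the unresolved genes and so understate the depth. At most 0.01% of the values above 0 were shared exactly by any pair of libraries.

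Differential expression was tested with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a mean trend) on log2(RPKM + 0.5), for genes with a mean RPKM of at least 0.5 over the libraries of the experiment. Each experiment was fitted at once with 4 group means, for 11439 genes in the Bmal1 experiment and 12738 in the Nr1d1 experiment. The contrasts were knockout against control at CT0 and at CT12, CT12 against CT0 in control and in knockout livers, and the interaction of genotype and time. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Because 0.5 is added to RPKM, the log2 difference of a gene with low RPKM is understated. Errors of log2 differences are standard errors of the fit, and errors of RPKM and of shares are standard deviations between libraries.

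Whether the replicate number paired the livers was checked by correlating, across genes, the deviations of libraries with the same number. In the Bmal1 experiment these correlations lay between -0.04 and 0.12. In the Nr1d1 experiment they lay between 0.82 and 0.88. Only replicate 2 of the Nr1d1 experiment is described as paired-end in the labels, and its RPKM sums over gene transcripts were 2099302 to 2211054, against 588418 to 875424 in replicate 1. For the Nr1d1 experiment the values with replicate number as a block are therefore given beside the values without it, and log2 differences and standard errors printed for single genes are those of the blocked fit.

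Gene lists and the rule for named genes were fixed before the data were examined. There were 15 pathway lists and 10 lists of cell type markers. The pathway lists covered E-box clock genes, REV-ERB-repressed clock genes, xenobiotic metabolism, cholesterol synthesis, lipogenesis, bile acid synthesis and transport, fatty acid oxidation, glucose and glycogen metabolism, heat shock and protein folding, immediate-early genes, the cell cycle, the acute phase response, male-biased liver genes, female-biased liver genes and the lnc-Crot neighbourhood. The marker lists covered hepatocytes, cholangiocytes, Kupffer cells or macrophages, endothelial cells, stellate cells or fibroblasts, neutrophils, lymphocytes, erythroid cells, adipocytes and pancreatic acinar cells. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a kind within a contrast. The lists overlap, so 1 gene can count in more than 1 list. Some single genes counted in the lists are not reported here. Lists with fewer than 3 members tested were not tested.

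The named genes of a contrast were the targeted gene, the members of the clock lists, the 8 largest called rises and 8 largest called falls without overlap between the libraries of both groups and with a mean RPKM of at least 1 in one group, up to 4 members of each other list by lowest p, and the genes around lnc-Crot. For the interaction, absence of overlap was not asked. Not every gene that the rule admits is named. List members named beyond the first 4, and genes named from the blocked fits of the Nr1d1 experiment, were chosen after their values were seen.

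For 4C, the fragment with the highest count in all 6 libraries was taken as the bait. Fragment starts are printed with 1 added to the deposited start. Fragment counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest with TMM factors and filterByExpr) and again with DESeq2 1.42.0. The share of counts within 1 Mb of the bait, without the 10 kb around it, was compared with an exact two-sided permutation test, which with 3 livers against 3 cannot give a p below 0.1. PCR reads carry no molecular identifiers here, so counting error was not used as the error of a share.

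The pipeline was tested on simulated data. With the spread and group sizes of the Bmal1 experiment at CT12, 74 of 100 genes changed by a log2 of 1 and 96 of 100 changed by a log2 of 2 were recovered by limma, and 11 of 181 calls were unchanged genes. With those of the Nr1d1 experiment, 0 of 100 at either size were recovered without a block. With the block, 14 of 100 and 76 of 100 were recovered, and 9 of 99 calls were unchanged genes. A simulated list change was recovered by camera at the preset correlation in both experiments, and with an estimated correlation only in the Bmal1 experiment. The simulated genes were drawn independently, with 1 changed list per experiment. The simulation therefore does not test the preset correlation for lists whose genes move together. Of 40 fragments changed by a log2 of 2 among 178 in simulated 4C data, edgeR recovered 0, and 18 when the dispersion was set to 0.1 of that of the real libraries.

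The alternatives fixed before the data were examined were other pseudocounts, other filters, quantile normalization, TMM scaling, a replicate block, limma without a trend, only the compared groups in the fit, and leaving out each library in turn. For 4C they were DESeq2, RLE factors, no filter, other windows, other distances left out around the bait and leaving out each library. Added after seeing the data were edgeR on the recovered reads, the mean over a gene's transcripts, TMM scaling with the block, the block without 1 Nr1d1 knockout library of CT0, the block with the level of Ddx3y as a covariate, 4C counts summed in 20 kb windows and 4C counts of 10 or fewer set to 0. No value is given for the lnc-Crot transcript, because it could not be matched by identifier or position. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.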

Results

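Livers of 8-week-old mice were collected after 2 days in constant darkness, at CT0 (the time at which the lights had come on) and CT12. RNA was sequenced from mice labelled as liver-specific knockouts of Bmal1, which encodes the activator BMAL1 (gene symbol Arntl) of the circadian clock, and from mice labelled as knockouts of Nr1d1, which encodes the clock repressor REV-ERBα, each with control mice. The comparisons ask how each knockout changes the liver transcriptome at opposite phases of the day. The 4C libraries ask which regions of chromosome 5 lie near lnc-Crot, a long noncoding RNA locus, at CT6 and CT18. Recovered reads on the gene transcripts that could be resolved were 8.55 M to 14.22 M in the 12 Bmal1 libraries (n = 3 per group). In the 8 Nr1d1 libraries (n = 2 per group) they were 26.67 M to 48.12 M. Both leave out the most abundant genes. The 4C libraries held 876104, 1852389 and 864391 counts at CT6 and 2671527, 1935157 and 1585870 at CT18 on chromosome 5.

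The targeted gene of the Bmal1 experiment, Arntl, was measured over its whole transcript, so that a partial deletion cannot be seen in these values. In control livers Arntl stood at 15.7 to 16.35 RPKM at CT0 and 0.68 to 1.26 at CT12. In livers labelled Bmal1 knockout it stood at 5.73 to 7.45 RPKM at CT0 and 3.59 to 4.37 at CT12. Arntl was thus lower in knockout livers at CT0 (log2 -1.27 ± 0.16, adjusted p = 0.00191 by limma) and higher at CT12 (1.55 ± 0.16, adjusted p = 6.63e-05).

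At CT0, genes that rose in livers labelled Bmal1 knockout included the estrogen sulfotransferase Sult1e1 (log2 4.63 ± 0.76, adjusted p = 0.01), the cytochromes P450 Cyp2c55 (3.52 ± 0.33) and Cyp2b10 (2.85 ± 0.56). The glutathione S-transferases Gstm3 (3.16 ± 0.38) and Gstm2 (2.60 ± 0.23), between which reads may be shared, rose as well. Lipoprotein lipase, Lpl, rose by 2.64 ± 0.33 (adjusted p = 0.00225), the adipokine gene Serpina12 by 2.71 ± 0.47 and the neurotrophin receptor gene Ntrk2 by 2.61 ± 0.24. The largest falls were those of the thyroid hormone deiodinase Dio1 (-3.09 ± 0.16, adjusted p = 2.61e-06), the transporter Slc22a26 (-2.94 ± 0.43), AC163723.1 (-2.79 ± 0.41), Nat8 (-2.67 ± 0.26) and the lipid droplet gene Fitm1 (-2.57 ± 0.21). They were followed by Cyp4a12a (-2.25 ± 0.46), the small heat shock protein Hspb1 (-2.10 ± 0.33) and the carboxylesterase Ces1d (-1.94 ± 0.17).

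Of the 13 E-box clock genes, whose promoters are bound by BMAL1, 6 rose and 2 fell at CT0, and 7 and 2 did when adjusted over the list alone. Nr1d1 fell by 1.94 ± 0.37 (adjusted p = 0.0252) and its paralog Nr1d2 by 1.11 ± 0.24 (adjusted p = 0.0416). Per2 rose by 1.33 ± 0.20, Per3 by 0.96 ± 0.19, Cry2 by 0.69 ± 0.15, Tef by 0.98 ± 0.11 and Bhlhe40 by 1.10 ± 0.21. The camera test called the list upward (adjusted p = 5.26e-05; adjusted p = 0.0657 with an estimated correlation). Of 7 genes repressed by REV-ERB, 3 rose, among them Cry1 (1.73 ± 0.11) and Npas2 (0.96 ± 0.13), and Arntl itself fell (3 and 2 adjusted over the list alone). That list was called upward too (adjusted p = 0.0186; adjusted p = 0.39 with an estimated correlation). In fatty acid oxidation, 5 of 28 genes fell and 16 did when adjusted over the list alone (camera downward, adjusted p = 6.33e-13; adjusted p = 0.329 with an estimated correlation). They included Ppara, the nuclear receptor that drives this pathway (-0.63 ± 0.12), and the thiolases Acaa1a (-0.78 ± 0.15) and Acaa1b (-1.24 ± 0.25). In xenobiotic metabolism 5 of 23 genes rose and 2 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.197). Beside the rises named above, Cyp2c29 rose by 1.43 ± 0.17, and Cyp2a5 (-1.34 ± 0.20) and Cyp2a4 (-1.39 ± 0.24) fell, a pair so alike in sequence that their reads may be shared.

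In all, limma called 185 of 11439 genes at CT0, 104 higher and 81 lower in knockout livers. The 7 neutrophil markers were higher in knockout livers at CT0 by a median of 1.39 (0 called over all genes, 7 adjusted over the list alone; camera adjusted p = 1.18e-05, and 0.561 as the adjusted p with an estimated correlation). Albumin, Alb, the most abundant hepatocyte transcript, took 6.1% to 8.06% of the summed RPKM of a control library and 3.21% to 4.74% of a knockout library. It fell at both times (-0.93 ± 0.14 at CT0 and -1.05 ± 0.14 at CT12; 0.00 under quantile normalization, which fixes the top of each library). Leaving out 1 library lowered the count at CT0 to 82 without control CT0 replicate 2, 100 without control CT0 replicate 3, 113 without knockout CT0 replicate 1 and 100 without knockout CT0 replicate 3. With no filter on RPKM 116 genes were called, and 108 with only the compared groups in the fit. Leaving out 1 library also ended the calls of Cyp2b10, Serpina12, Cyp4a12a, Nr1d1, Nr1d2, Per3, Cry2, Bhlhe40, Cyp2a4, Acaa1a, Ppara and Acaa1b, for at least 1 choice of the library.

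At CT12 the lipid gene Elovl3, an elongase of very long chain fatty acids, stood at 7.21 ± 0.09 RPKM in control livers and 239.9 ± 54.96 in livers labelled Bmal1 knockout (SD, n = 3). This is a log2 rise of 4.94 ± 0.16 (adjusted p = 1.46e-08 by limma). Lpl rose by 4.05 ± 0.33, the phosphate transporter Slc34a2 by 3.81 ± 0.23, Loxl4 by 3.61 ± 0.24 and the cell cycle inhibitor Cdkn1a by 3.45 ± 0.41. Insig2, which retains the sterol sensor SCAP in the endoplasmic reticulum, rose by 3.32 ± 0.24, Gstm3 by 3.57 ± 0.38 and Cyp2c55 by 3.48 ± 0.33. The steepest falls were those of the G protein regulator Rgs16 (-5.28 ± 0.88, adjusted p = 0.0025), Cyp2a4 (-3.95 ± 0.24), Cyp2a5 (-3.91 ± 0.20) and the thioesterase Acot3 (-3.26 ± 0.45). Falls were also called in Col27a1 (-3.20 ± 0.30), the clock repressor Gm129 (-3.16 ± 0.41), Nat8 (-3.13 ± 0.26) and Cml5 (-3.03 ± 0.52).

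Among the 13 E-box clock genes, 6 fell at CT12 and 1 rose (7 and 1 adjusted over the list alone). Falls were measured in Nr1d2 (-2.07 ± 0.24), Per2 (-0.80 ± 0.20), Per3 (-1.71 ± 0.19), the transcription factors Dbp (-2.10 ± 0.29) and Tef (-0.96 ± 0.11), and Gm129. This list was called downward by camera at both correlations (adjusted p = 1.52e-07; adjusted p = 0.0188 with an estimated correlation). With replicate number as a block it was not called at the estimated one (adjusted p = 0.0958). Of the 7 genes repressed by REV-ERB 5 rose, over all genes and adjusted over the list alone, among them Arntl, Npas2 (2.93 ± 0.13), Clock (1.05 ± 0.16) and Cry1 (1.71 ± 0.11). The camera adjusted p was 1.52e-07 (adjusted p = 0.0551 with an estimated correlation).

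Called genes of sterol synthesis rose at CT12, and most called genes of fatty acid oxidation fell. In cholesterol synthesis 10 of 24 genes rose and 0 fell (14 adjusted over the list alone; camera adjusted p = 0.000109; adjusted p = 0.606 with an estimated correlation). They included the synthase Hmgcs1 (1.78 ± 0.27), the mevalonate kinase Mvk (0.88 ± 0.15), the squalene synthase Fdft1 (0.84 ± 0.15) and the isomerase Idi1 (0.80 ± 0.17). In fatty acid oxidation 12 of 28 genes fell and 2 rose (16 and 2 adjusted over the list alone; camera downward, adjusted p = 3.72e-13; adjusted p = 0.427 with an estimated correlation). Ppara fell by 1.05 ± 0.12, and the rises were those of Pdk4, a kinase that limits glucose oxidation (1.53 ± 0.26), and of Crot, the peroxisomal carnitine octanoyltransferase next to lnc-Crot (1.38 ± 0.30). In lipogenesis 4 of 24 genes fell and 1 rose (6 and 1 adjusted over the list alone; camera downward, adjusted p = 0.000228; adjusted p = 0.606 with an estimated correlation). The lipogenic regulators Srebf1 (-1.003 ± 0.21) and Mlxipl (-0.96 ± 0.23) and the desaturase Fads2 (-1.07 ± 0.14) were among the falls, and the gene that rose was Lpl.

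Glucose genes split at CT12, 2 of 21 rising and 2 falling (3 and 2 adjusted over the list alone; camera downward, adjusted p = 0.037; adjusted p = 0.734 with an estimated correlation). The liver glycogen synthase Gys2 (-1.89 ± 0.13) and the glucose transporter Slc2a2 (-1.30 ± 0.27) fell, and the glycogen-targeting subunit Ppp1r3c (1.99 ± 0.26) and the insulin receptor substrate Irs2 (1.33 ± 0.24) rose. Xenobiotic genes also split, with 5 of 23 rising and 5 falling (5 and 9 adjusted over the list alone) and a median of 0.00. Camera called the list downward (adjusted p = 0.037; adjusted p = 0.606 with an estimated correlation). Among 17 bile acid genes Hsd3b7, an enzyme of bile acid synthesis (1.39 ± 0.13), and the bile salt export pump Abcb11 (1.10 ± 0.11) rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.779). The cell cycle kinase Wee1, a target of the clock, fell by 1.39 ± 0.22. Of 12 female-biased liver genes 4 fell and 1 rose at CT12 (6 and 1 adjusted over the list alone), and camera called the list downward (adjusted p = 0.00261; adjusted p = 0.517 with an estimated correlation).

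At CT12 limma called 1107 genes, 739 higher and 368 lower in knockout livers. The higher share, 66.8%, depended on the scaling. With TMM factors 1049 genes were called, 507 higher and 542 lower. With edgeR on recovered reads 787 of 10459 were called, 393 higher and 394 lower, but the most abundant genes are absent from that fit. Neutrophil markers were higher by a median of 1.31 (2 of 7 called and 6 adjusted over the list alone; camera adjusted p = 0.0124; adjusted p = 0.869 with an estimated correlation). Erythroid markers were higher by 1.07 (2 of 5 called and 4 adjusted over the list alone; camera adjusted p = 0.133). The count fell to 713 without control CT12 replicate 3 and to 737 without knockout CT12 replicate 2, and the calls of Per2, Mlxipl and Crot were lost without at least 1 library. Of the genes called at CT0, 83 were also called higher and 55 also lower at CT12, against 6.72 and 2.61 if the calls were independent. The libraries of both times are distinct, but both comparisons share each gene's spread from 1 fit, so their calls are not fully independent.

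**Figure D1:**
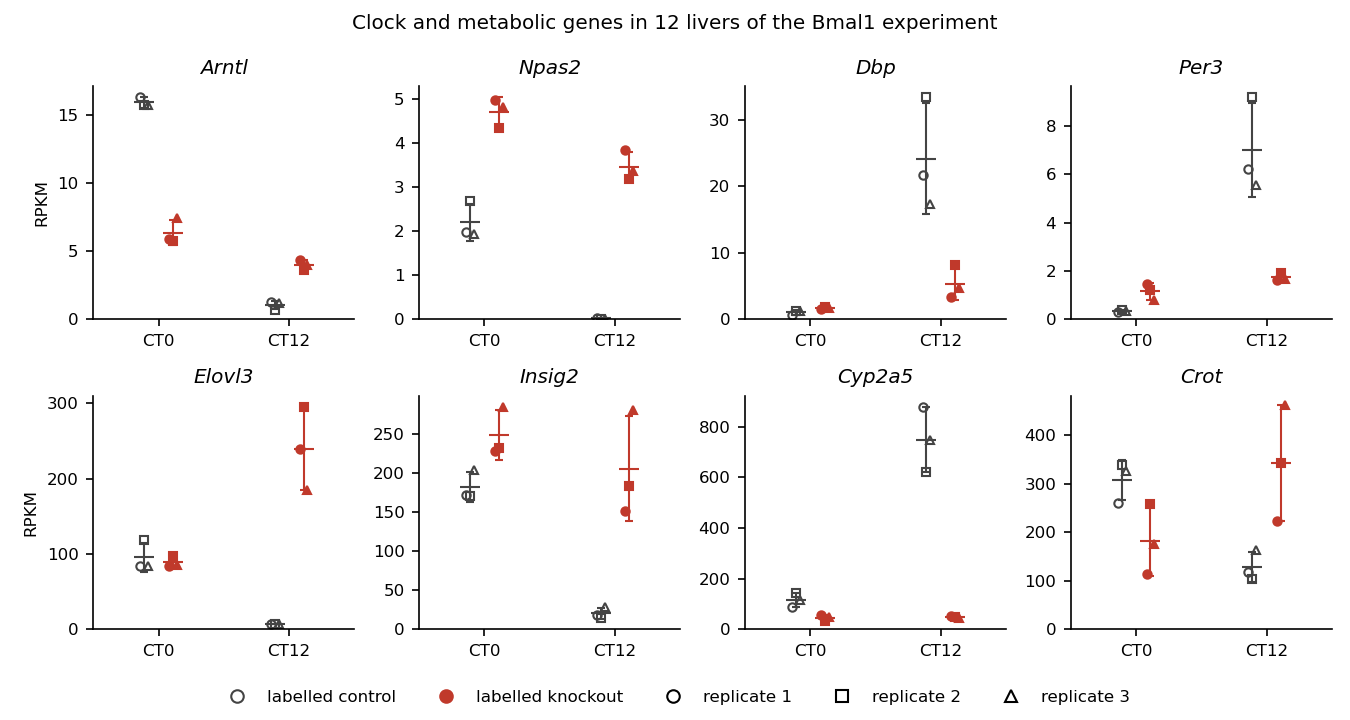
RPKM (vertical axes) of Arntl, Npas2, Dbp, Per3, Elovl3, Insig2, Cyp2a5 and Crot in control and Bmal1 knockout livers at CT0 and CT12, where each point is a library and bars give the mean and SD of 3. Elovl3 stood at 7.21 in control livers at CT12 and at 239.9 in knockout livers.

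In control livers of the Bmal1 experiment, Gm129 rose between CT0 and CT12 by 4.85 ± 0.41, the deubiquitinase Usp2 by 4.03 ± 0.32, Dbp by 3.98 ± 0.29 and Alas1, the first enzyme of heme synthesis, by 3.97 ± 0.39 (adjusted p = 1.91e-05, 1.26e-05, 7.66e-06 and 6.81e-05 by limma). Rgs16 (3.603 ± 0.88), the lipid transporter Mfsd2a (3.18 ± 0.52), Per3 (3.13 ± 0.19) and the phosphatidate phosphatase Lpin1 (3.05 ± 0.48) rose as well. Falls were called in Arntl (-3.43 ± 0.16, adjusted p = 2.12e-07), Elovl3 (-3.62 ± 0.16), the tubulin Tubb2a (-3.54 ± 0.29), Insig2 (-3.19 ± 0.24), Spon2 (-2.79 ± 0.23) and the water channel Aqp8 (-2.67 ± 0.32). Reads of Tubb2a and Tubb2b may be shared.

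Of 13 E-box clock genes 10 rose in control livers and 0 fell (11 adjusted over the list alone), with a median of 1.94. Among them were Per1 (2.97 ± 0.39), Per2 (2.59 ± 0.20), Tef (2.35 ± 0.11) and Nr1d2 (1.94 ± 0.24). Camera called this list at both correlations (adjusted p = 5.32e-18; adjusted p = 0.000763 with an estimated correlation). Of the 7 genes repressed by REV-ERB 4 fell and 1 rose (4 and 1 adjusted over the list alone; camera downward, adjusted p = 0.00261; adjusted p = 0.304 with an estimated correlation). Beside Arntl, the falls were those of Npas2 (-2.37 ± 0.13), Clock (-0.94 ± 0.16) and Nfil3 (-1.16 ± 0.16). In xenobiotic metabolism 7 of 23 genes rose (7 adjusted over the list alone; camera adjusted p = 3.84e-06; adjusted p = 0.21 with an estimated correlation). The rises included Cyp2a5 (2.71 ± 0.20), Cyp2a4 (2.60 ± 0.24) and Por, the electron donor of cytochromes P450 (1.84 ± 0.21). Bile acid genes split, 4 of 17 rising and 2 falling (5 and 4 adjusted over the list alone; camera adjusted p = 0.135). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.90 ± 0.28, while Hsd3b7 (-1.62 ± 0.13) and Abcb11 (-1.17 ± 0.11) fell. Of 21 glucose genes 5 rose and 4 fell (8 and 4 adjusted over the list alone; camera upward, adjusted p = 0.00427; adjusted p = 0.581 with an estimated correlation). Gys2 rose by 1.61 ± 0.13 and the gluconeogenic enzyme Pck1 by 1.33 ± 0.23, and Ppp1r3c fell by 1.73 ± 0.26. Fatty acid oxidation had 4 rises and 2 falls among 28 genes (5 and 2 adjusted over the list alone; camera upward, adjusted p = 5.26e-05; adjusted p = 0.581 with an estimated correlation). Female-biased genes had 2 rises among 12 (3 adjusted over the list alone; camera adjusted p = 0.00427; adjusted p = 0.576 with an estimated correlation).

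Camera called 5 of 8 lists of cell type markers downward at CT12 in control livers, and 0 with an estimated correlation. The neutrophil calprotectin genes S100a8 (-2.81 ± 0.45) and S100a9 (-2.72 ± 0.40) were among the largest falls. Of 7 neutrophil markers 6 fell, with a median of -1.86 (7 adjusted over the list alone; camera adjusted p = 0.000178; adjusted p = 0.389 with an estimated correlation). Kupffer cell markers had a median of -0.65 with 1 of 10 called and 8 adjusted over the list alone (camera adjusted p = 0.00289; adjusted p = 0.389 with an estimated correlation). Erythroid (median -0.96, camera adjusted p = 0.0466, and 0.0534 with replicate number as a block), endothelial (-0.53, 0.0362) and stellate cell (-0.64, 0.0362) markers were called downward as well, with 2 of 5, 1 of 9 and 1 of 10 genes called, and each had an adjusted p of 0.389 with an estimated correlation. Cholangiocyte (0.095), hepatocyte (0.141) and lymphocyte (0.47) markers were not called by camera. Limma called 1239 genes over time in control livers, 389 higher and 850 lower at CT12. With TMM factors 1234 were called, 49.9% of them higher, so the excess of falls depended on the scaling. Without control CT0 replicate 2 or 3 the count was 647 or 704, and without control CT12 replicate 1 or 3 it was 735 or 633, and the calls of Rgs16, Crot and Dmtf1 were lost without at least 1 library.

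In livers labelled Bmal1 knockout fewer genes were called between CT0 and CT12. Mfsd2a (2.49 ± 0.52), Usp2 (2.44 ± 0.32) and Alas1 (2.41 ± 0.39) rose here too. Further rises were those of Cdkn1a (2.26 ± 0.41), Pck1 (2.03 ± 0.23, adjusted p = 0.00206 by limma), Cyp4a12b (1.95 ± 0.35), the transcription factor Zbtb16 (1.92 ± 0.25) and Dio1 (1.83 ± 0.16). Elovl3 rose by 1.40 ± 0.16 (adjusted p = 0.00244). Neutrophil granule genes fell, namely S100a8 (-2.48 ± 0.45), Camp (-2.40 ± 0.53), S100a9 (-2.29 ± 0.40), Ltf (-2.03 ± 0.47) and Mpo (-1.90 ± 0.43). So did Slc17a8 (-1.94 ± 0.39), Aqp8 (-1.67 ± 0.32) and Acmsd (-1.63 ± 0.31). Arntl differed by -0.61 ± 0.16 (adjusted p = 0.0689) between the times.

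Of the 13 E-box clock genes, Per1 (1.75 ± 0.39) and Dbp (1.36 ± 0.29) rose in knockout livers, and 6 rose and 1 fell adjusted over the list alone (camera upward, adjusted p = 0.00321; adjusted p = 0.263 with an estimated correlation). No gene of the REV-ERB-repressed list was called, and 3 fell adjusted over the list alone (camera downward, adjusted p = 0.0144; adjusted p = 0.43 with an estimated correlation). In lipogenesis 3 of 24 genes fell and 1 rose (13 and 3 adjusted over the list alone; camera downward, adjusted p = 0.000454; adjusted p = 0.691 with an estimated correlation). The falls were Srebf1 (-1.26 ± 0.21), Mlxipl (-1.03 ± 0.23) and the acyltransferase Agpat2 (-0.52 ± 0.11), and the lipid droplet gene Plin4 rose by 1.48 ± 0.25. The carnitine palmitoyltransferase Cpt1a rose by 1.04 ± 0.15 and the phospholipid transporter Abcb4 by 0.67 ± 0.13. Male-biased liver genes were called upward (2 of 17 rose, 5 adjusted over the list alone; camera adjusted p = 8.88e-06; adjusted p = 0.43 with an estimated correlation). Between libraries of the same number their medians were 1.38 and 1.52 in replicates 1 and 2, and -0.06 in replicate 3, where 10 of 17 were lower. Female-biased genes had 0 calls by limma (camera adjusted p = 0.733). Neutrophil markers had a median of -2.20, with 4 of 7 called and 7 adjusted over the list alone (camera adjusted p = 1.08e-07; adjusted p = 0.313 with an estimated correlation). Kupffer cell (median -0.39, camera adjusted p = 0.011), endothelial (-0.53, 0.00433) and stellate cell (-0.58, 0.00215) markers were called downward too, with 0 genes called over all genes, 0, 2 and 5 adjusted over the list alone, and an adjusted p of 0.484 each with an estimated correlation. Limma called 217 genes, 104 higher and 113 lower at CT12. The count was 48 without knockout CT0 replicate 3, 51 without knockout CT12 replicate 1, 92 without knockout CT12 replicate 2, and 25 with only the compared groups in the fit. Of the 25 genes named as called, only Usp2, Pck1, Zbtb16, Dio1, Elovl3 and Cpt1a kept the call without each library in turn.

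The interaction tests directly whether the change from CT0 to CT12 differed between genotypes, and shares all its libraries with the comparisons above. The largest positive interaction was that of Elovl3 (log2 5.02 ± 0.23, adjusted p = 6.87e-07 by limma), which fell over the day in control livers and rose in knockout livers. Cdkn1a (3.23 ± 0.58), Tubb2a (2.93 ± 0.42), Insig2 (2.88 ± 0.35), Arntl (2.82 ± 0.22), Spon2 (2.51 ± 0.33) and the mitochondrial chaperone gene Clpx (2.40 ± 0.21) followed. Negative interactions were led by Gm129 (-3.64 ± 0.58), Per3 (-2.67 ± 0.27), Dbp (-2.62 ± 0.41), Cyp2a5 (-2.56 ± 0.29), Cyp2a4 (-2.56 ± 0.34), D0H4S114 (-2.35 ± 0.42), Wee1 (-2.33 ± 0.32) and the uridine phosphorylase Upp2 (-2.16 ± 0.27). Of the 13 E-box clock genes 6 were called, all negative (9 negative and 1 positive adjusted over the list alone), and camera called the list at both correlations (adjusted p = 1.04e-17; adjusted p = 0.00081 with an estimated correlation). The 7 genes repressed by REV-ERB had 3 positive calls and 1 negative (4 and 1 adjusted over the list alone; camera adjusted p = 0.00416; adjusted p = 0.323 with an estimated correlation). The acute phase list had 3 of 24 positive calls (7 adjusted over the list alone; camera adjusted p = 2.57e-05; adjusted p = 0.323 with an estimated correlation). The xenobiotic list had 3 of 23 negative calls (3 adjusted over the list alone; camera adjusted p = 7.02e-06; adjusted p = 0.248 with an estimated correlation). No lipogenesis gene was called by limma, where 4 were negative adjusted over the list alone (camera downward, adjusted p = 2.62e-06; adjusted p = 0.323 with an estimated correlation). Female-biased genes had 1 negative call and were called downward by camera (adjusted p = 0.000332; adjusted p = 0.323 with an estimated correlation), and male-biased genes had 1 positive call (camera upward, adjusted p = 0.0151; adjusted p = 0.53 with an estimated correlation).

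Crot stood at 307.65 ± 41.48 RPKM in control livers at CT0 and 127.89 ± 30.74 at CT12, and at 182.52 ± 72.4 and 342.39 ± 119.93 in knockout livers (SD, n = 3). It fell over time in controls (-1.28 ± 0.30, adjusted p = 0.0203) and had an interaction of 2.20 ± 0.43 (adjusted p = 0.0279 by limma). Its differences at CT0 (-0.82 ± 0.30, adjusted p = 0.24) and over time in knockout livers (0.92 ± 0.30, adjusted p = 0.129) were not called. With 1 library left out the adjusted p of Crot reached 0.0533 at CT12, 0.0714 over time in controls and 0.0823 in the interaction. Abcb1a, a drug efflux pump gene of the same neighbourhood on chromosome 5, moved the other way. It rose over time in controls (0.98 ± 0.18), was lower in knockout livers at CT12 (-1.47 ± 0.18) and had an interaction of -1.20 ± 0.26 (adjusted p = 0.0417). Among the 8 neighbourhood genes tested, 0 were called at CT0 by limma, and 1 rose and 1 fell at CT12 (2 and 1 adjusted over the list alone). Camera did not call the list at either time (adjusted p = 0.0608 and 0.838; adjusted p = 0.289 and 0.854 with an estimated correlation). It did at CT0 with replicate number as a block, at the preset correlation (adjusted p = 0.0421). In controls over time 1 rose and 2 fell, the smallest change being that of Dmtf1 (-0.38 ± 0.11, adjusted p = 0.0432).

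Limma called 150 genes in the interaction, 111 positive and 39 negative (87 and 59 of 146 with TMM factors). Of these 150, 141 were also called over time in control livers and 144 between genotypes at CT12, against 18 at CT0. Among the 1239 genes called over time in control livers, 1154 had a smaller absolute log2 difference in knockout livers and 1010 had the same sign. Of the 217 called over time in knockout livers, 145 had a smaller one in controls, and both counts follow in part from choosing genes by their change in the first group. The interaction count was 96, 81 and 87 without control CT0 replicate 1, 2 and 3, 92 and 83 without control CT12 replicate 1 and 3, and 93 and 88 without knockout CT12 replicate 2 and 3. Among the named genes, Cdkn1a, Crot, D0H4S114, Clock, Ppp1r3c, Abcb11, Fga, Fgg, Lbp, Por and Abcb1a lost the call without at least 1 library.

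**Figure D2:**
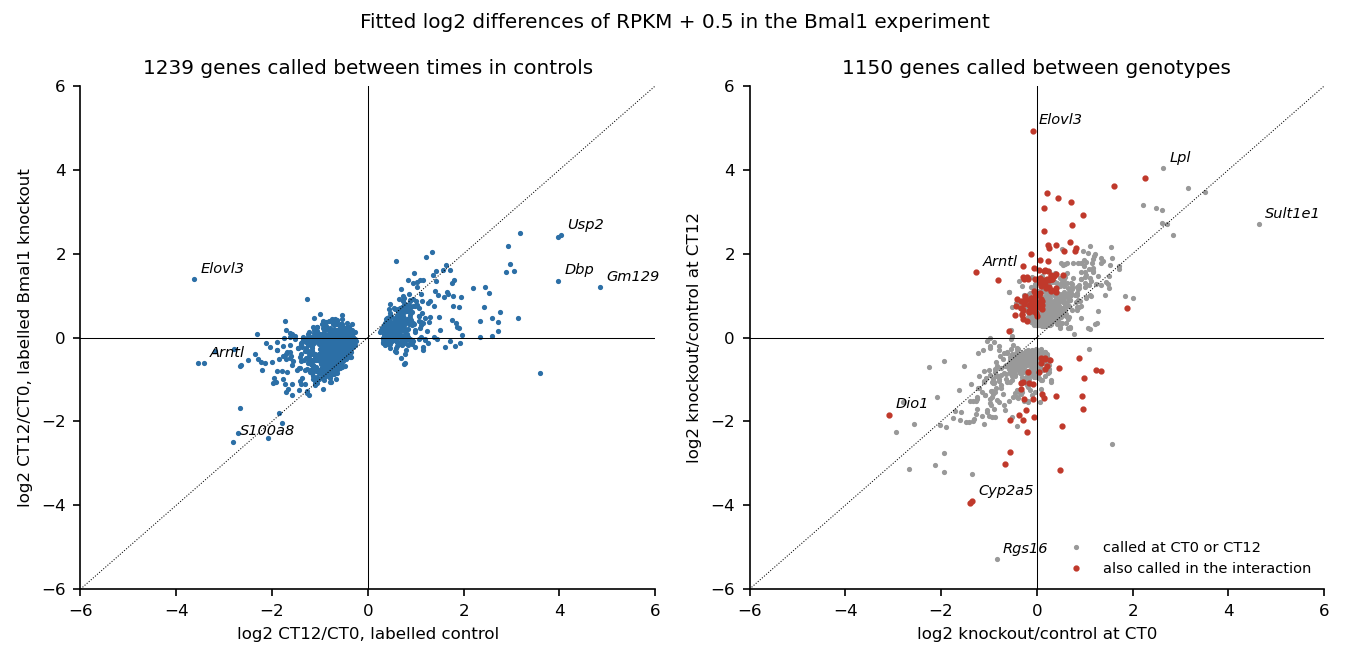
Log2 differences of single genes (points) in the Bmal1 experiment, on the left CT12 against CT0 in control (horizontal) and knockout livers (vertical) for the 1239 genes called in controls, on the right knockout against control at CT0 (horizontal) and CT12 (vertical) for the 1150 genes called at either time. The dotted line marks equal values, and 147 of the genes on the right were also called in the interaction.

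In the Nr1d1 experiment the targeted gene itself was higher in livers labelled knockout in 3 of 4 comparisons within a replicate. Nr1d1 stood at 0.37 and 21.97 RPKM in the control libraries of replicates 1 and 2 at CT0 and at 3.45 and 33.42 at CT12. It stood at 6.10 and 32.90 at CT0 and 11.07 and 28.40 at CT12 in livers labelled Nr1d1 knockout. Its log2 differences were 1.75 at CT0 and 0.66 at CT12, both uncalled, and the whole-transcript values cannot show a partial deletion. The replicates also differed in their RPKM scale and in the expression of Y-linked genes. Ddx3y was at 5.64 RPKM in the control and 5.39 in the knockout library of replicate 1 at CT0, at 0.056 and 0.014 in the libraries of replicate 1 at CT12, and at 0 in all 4 libraries of replicate 2.

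Without a block limma called 0 of 12738 genes in each of the 5 Nr1d1 contrasts, with 0, 4, 12, 7 and 0 genes at an unadjusted p under 0.05 in the order CT0, CT12, control time, knockout time and interaction. With edgeR on recovered reads, of 11747 genes, 0 were called as well, with 55, 140, 290, 150 and 81 at an unadjusted p under 0.05. With replicate number as a block, limma called 0 genes at CT0, 5 at CT12, 45 over time in controls, 7 over time in knockout livers and 0 in the interaction. At an unadjusted p under 0.05 there were 575, 579, 1031, 1833 and 538. With edgeR and the block 1, 10, 60, 4 and 2 were called.

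Over time in control livers, several clock genes were among the blocked calls. Dbp rose by 5.22 ± 0.28 (adjusted p = 0.000436), Usp2 by 3.57 ± 0.19, Per3 by 3.38 ± 0.32, Per1 by 3.04 ± 0.20, D0H4S114 by 2.97 ± 0.19 and Alas1 by 2.83 ± 0.36 in the blocked limma fit. Smaller rises were those of Lpin1 (2.74 ± 0.40), Cyp2a5 (2.53 ± 0.25), Wee1 (2.53 ± 0.25), Tef (2.25 ± 0.22) and Gys2 (1.45 ± 0.20). Gm129 rose from a value listed as 0 in the control CT0 library of replicate 1 (adjusted p = 0.000436). Falls were called in Arntl (-3.79 ± 0.31, adjusted p = 0.00311), Ppp1r3c (-2.96 ± 0.28), the choline kinase Chka (-2.76 ± 0.21), Insig2 (-2.35, adjusted p = 0.0231) and Tubb2a (-2.90, adjusted p = 0.0082). Of 13 E-box clock genes 5 rose with the block (10 adjusted over the list alone; camera adjusted p = 5.5e-20; adjusted p = 0.0681 with an estimated correlation), with medians of 2.18 within replicate 1 and 1.5 within replicate 2. The 7 genes repressed by REV-ERB had 1 fall, Arntl (5 adjusted over the list alone; camera downward, adjusted p = 1.47e-09; adjusted p = 0.106 with an estimated correlation), with medians of -1.13 and -1.52 within the replicates.

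Sex-biased liver genes moved over time within replicate 1 of the control livers. Between CT0 and CT12 the 4 Y-linked genes fell to near 0 there (median log2 -3.05), all 17 male-biased genes were lower (-3.09) and all 18 female-biased genes were higher (5.54), whereas in replicate 2 the medians were 0.28 and -0.41. Y-linked expression differed between the times in both genotypes of replicate 1, so time and a difference in sex cannot be told apart within that replicate. The changes over time called with the block rest in part on it. With the block, female-biased genes had 0 calls by limma and 5 adjusted over the list alone (camera adjusted p = 3.14e-08; adjusted p = 0.489 with an estimated correlation). Male-biased genes had 0 calls (camera downward, adjusted p = 2.34e-08; adjusted p = 0.489 with an estimated correlation). Xenobiotic genes, several of them sex-biased, had 3 of 24 rises (6 adjusted over the list alone; camera adjusted p = 0.00478; adjusted p = 0.733 with an estimated correlation). With the level of Ddx3y as a covariate beside the block, 48 genes were called over time in controls.

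**Figure D3:**
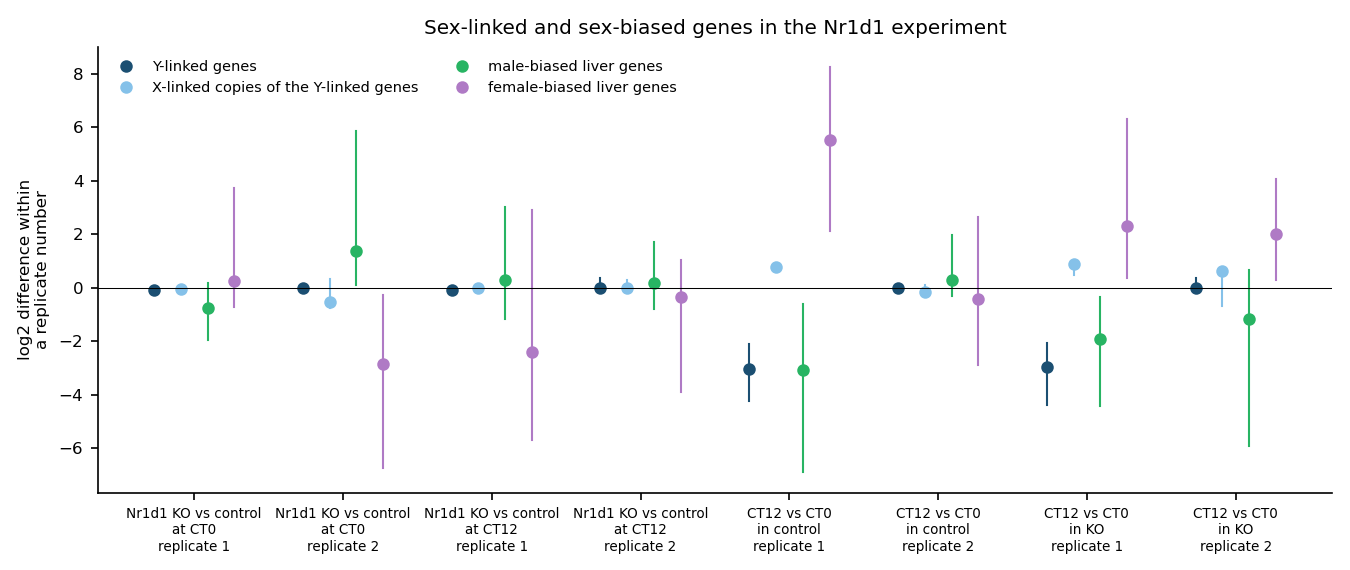
Median log2 differences (dots) and range from the lowest to the highest gene (lines) of 4 Y-linked genes, their 4 X-linked copies, 17 male-biased and 18 female-biased liver genes within each replicate number of the Nr1d1 experiment. The female-biased median was 5.54 between CT12 and CT0 in control livers of replicate 1 and -0.41 in replicate 2.

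In livers labelled Nr1d1 knockout, Arntl was nearly equal at both times, with 8.03 and 19.91 RPKM at CT0 and 8.00 and 19.28 at CT12 in replicates 1 and 2. The log2 difference was -0.03 ± 0.31 (adjusted p = 0.985 in the blocked limma fit). The 7 genes that rose over time with the block were Gm129 (3.65 ± 0.24), Lpin1 (3.62 ± 0.40), Usp2 (3.45 ± 0.19), Zbtb16 (2.68), Per1 (2.32 ± 0.20), Arhgef26 (2.13) and Coq10b (1.79). Their adjusted p lay between 0.00133 (Usp2) and 0.04 (Lpin1 and Arhgef26). E-box clock genes had 2 rises among 13 (8 adjusted over the list alone; camera adjusted p = 3.15e-09; adjusted p = 0.219 with an estimated correlation), with medians of 1.37 and 1.26 within the replicates. Of 24 cholesterol genes 0 were called by limma and 12 were higher adjusted over the list alone (camera adjusted p = 2.81e-07; adjusted p = 0.411 with an estimated correlation). Female-biased genes were higher at CT12 within both replicates, by medians of 2.30 and 2.01, and male-biased genes lower by medians of -1.93 and -1.18. In replicate 1 Ddx3y was at 5.39 RPKM in the knockout library of CT0 and at 0.014 in that of CT12. Time thus cannot be told apart there from a difference in sex. In replicate 2 the knockout CT0 library stood apart from its control in these genes (female-biased median -2.86). Other lists fell in replicate 2 alone, with medians of -1.90 for erythroid and -1.12 for neutrophil markers and -0.78 for acute phase genes, against 0.10, 0.18 and 0.47 in replicate 1. With the block camera called the erythroid markers (adjusted p = 6.47e-05; adjusted p = 0.516 with an estimated correlation) and the acute phase genes (adjusted p = 0.00348; adjusted p = 0.551 with an estimated correlation) downward. Stellate cell markers were called upward (medians of 0.51 and 0.77; camera adjusted p = 0.0158; adjusted p = 0.516 with an estimated correlation). Without the knockout CT0 library of replicate 2 the blocked count over time was 1, and with Ddx3y as a covariate it was 1.

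Between genotypes at CT12, Arntl was at 0.60 and 1.30 RPKM in the control libraries and 8.00 and 19.28 in those labelled Nr1d1 knockout, with a log2 rise of 3.21 ± 0.31 with the block (adjusted p = 0.0395 by limma). Lpl (2.23 ± 0.23), Chka (2.02 ± 0.21) and Ethe1, a mitochondrial sulfur dioxygenase (1.69 ± 0.18), rose at the same adjusted p, and D0H4S114 fell by 2.34 ± 0.19 (adjusted p = 0.0313). Beside Arntl, 0 other genes repressed by REV-ERB were called, while 3 were higher and 1 lower adjusted over the list alone (camera upward, adjusted p = 0.000662; adjusted p = 0.429 with an estimated correlation). The medians within the replicates were 0.52 and 0.64. Cholesterol genes had 0 calls by limma and 4 adjusted over the list alone (camera upward, adjusted p = 1.16e-11; adjusted p = 0.429 with an estimated correlation). Lipogenesis had 1 rise, Lpl, and 1 adjusted over the list alone (camera upward, adjusted p = 0.000329; adjusted p = 0.429 with an estimated correlation). Female-biased genes had 0 calls and were called downward by camera (adjusted p = 2.97e-07; adjusted p = 0.517 with an estimated correlation), with medians of -2.41 in replicate 1 and -0.34 in replicate 2. Camera with the block also called cholangiocyte (adjusted p = 0.000592; adjusted p = 0.411 with an estimated correlation), endothelial (0.00401; 0.898) and stellate cell markers (0.005; 0.898) upward, where limma called 0 genes. Their medians were 0.50, 0.07 and 0.08 within replicate 1 and 0.99, 0.57 and 0.84 within replicate 2. Neutrophil (-0.15 and 1.04) and erythroid markers (1.02 and -0.65) moved in opposite directions in the replicates. With TMM factors and the block 2 genes were called, and 4 without the knockout CT0 library of replicate 2.

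At CT0 the blocked limma fit called 0 genes between genotypes, and Dbp, the gene nearest to the threshold among those named, had a log2 difference of 3.10 ± 0.28 (adjusted p = 0.0664). Hspb1 differed by -2.16 (adjusted p = 0.0686). Of the E-box clock genes 5 were higher and 1 lower adjusted over the list alone (camera upward, adjusted p = 2.7e-10; adjusted p = 0.179 with an estimated correlation), and the medians within the replicates were 0.77 and 0.57. Genes repressed by REV-ERB had 3 lower adjusted over the list alone (camera downward, adjusted p = 0.000738; adjusted p = 0.42 with an estimated correlation). The knockout CT0 library of replicate 2 stood apart in the sex-biased genes, with all 17 male-biased genes above the control (median 1.38) and all 18 female-biased genes below it (-2.86), against medians of -0.77 and 0.24 in replicate 1. Marker lists moved in that comparison as well, with medians of 1.78 for neutrophil, 1.95 for erythroid and 0.71 for Kupffer cell markers and 0.79 for acute phase genes, against -0.05, 0.60, 0.06 and -0.12 in replicate 1. In the blocked interaction Arntl had a log2 value of 3.77 ± 0.43 (adjusted p = 0.167). Camera called the genes repressed by REV-ERB upward in the interaction (5 adjusted over the list alone; adjusted p = 6.85e-06; adjusted p = 0.214 with an estimated correlation). The E-box clock genes were called downward (2 adjusted over the list alone; adjusted p = 1.23e-07; adjusted p = 0.214 with an estimated correlation).

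**Figure D4:**
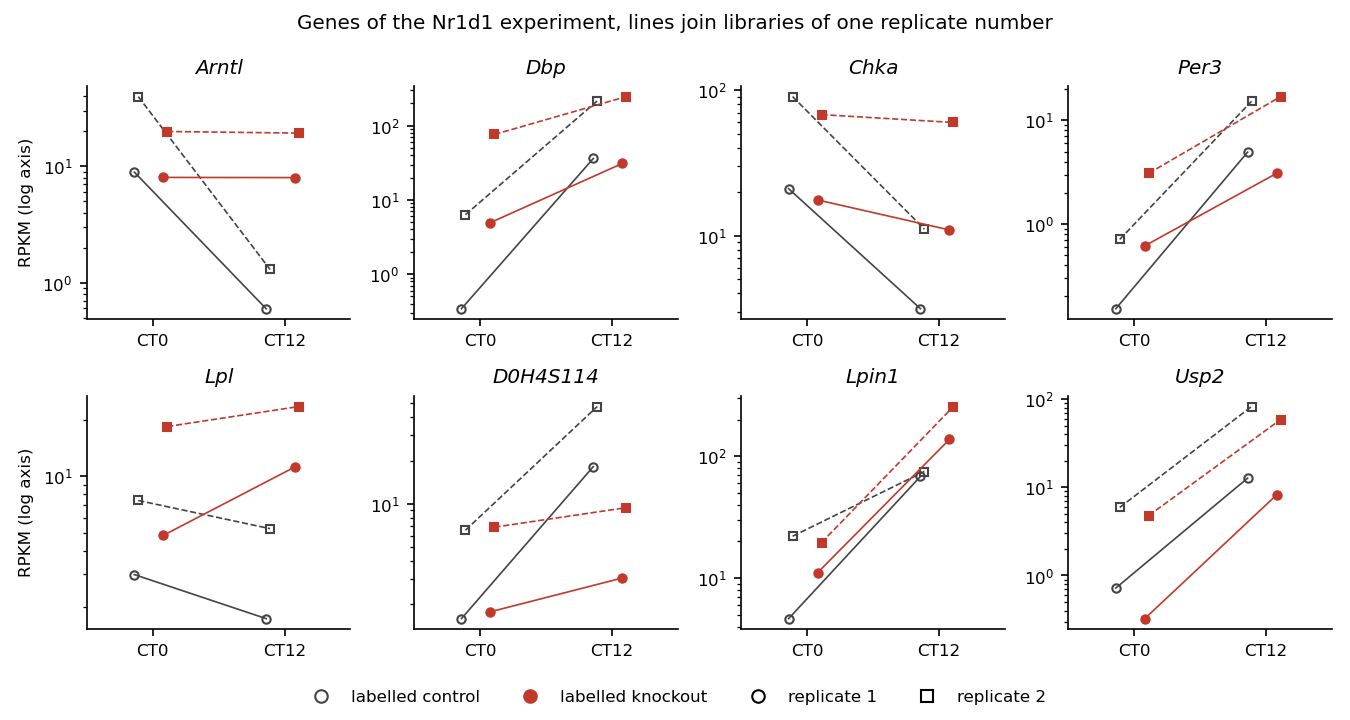
RPKM on a log axis of Arntl, Dbp, Chka, Per3, Lpl, D0H4S114, Lpin1 and Usp2 at CT0 and CT12 in control and Nr1d1 knockout livers, where each point is a library and lines join the libraries of replicate 1 (solid) and replicate 2 (dashed). Arntl fell over time in both control replicates, to 0.60 and 1.30 RPKM, and stood at 8.00 and 19.28 in knockout livers at CT12.

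The effects of both knockouts were compared across the 11143 genes tested in both experiments, which share no library. The rank correlation (Spearman) of the log2 differences across genes was 0.283 at CT12 and 0.079 at CT0, where genes are not independent replicates and no p is given. The 4 genes called higher at CT12 in the blocked Nr1d1 fit (Arntl, Chka, Ethe1 and Lpl) were all among the 729 called higher in the Bmal1 experiment, against 0.262 if the calls were independent, and D0H4S114 was called lower in both. With TMM factors or Ddx3y beside the block, Arntl and D0H4S114 kept the Nr1d1 call at CT12, while Chka, Ethe1 and Lpl lost it. With 1 Nr1d1 library left out and no block, the Nr1d1 effect also holds the difference between the replicates. In such fits the correlation at CT12 was 0.187 without control replicate 1, 0.13 without control replicate 2, 0.177 without knockout replicate 1 and 0.154 without knockout replicate 2. At CT0 it lay at 0.136 without control replicate 1 of the Bmal1 experiment, and at 0.011, -0.024 and 0.131 without control replicate 2, knockout replicate 1 and knockout replicate 2 of the Nr1d1 experiment.

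In the 4C libraries, which list ligation products of the lnc-Crot bait, the fragment with the most counts lay on chromosome 5 at 9042518 to 9044511 (mm9). It held 14.535% ± 1.719 of the counts at CT6 and 10.899% ± 1.268 at CT18 (SD, n = 3). Beyond the 10 kb around the bait, 48.91% ± 5.13 of the counts fell within 1 Mb at CT6 and 57.27% ± 2.45 at CT18, with single livers at 50.01%, 53.39% and 43.32% and at 59.62%, 54.73% and 57.46%. The difference of 8.36 percentage points had an exact two-sided permutation p of 0.1, the smallest that 3 livers against 3 can give. A paired sign-flip permutation test on the replicate number gave p = 0.25, the smallest that 3 pairs can give. With a library left out the difference lay between 5.56 points, without CT6 replicate 3, and 10.6, without CT6 replicate 2. The 200 kb window differed by 6.13 points (exact permutation p = 0.3). The share partly followed the depth of the libraries. CT6 replicates 3 and 1 had the fewest counts (864391 and 876104) and the lowest shares, and CT18 replicate 1 had the most (2671527) and the highest share. CT6 replicate 2 had more counts than CT18 replicate 3 (1852389 against 1585870) but a lower share. An effect of depth on the share was not tested.

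The regions with the largest mean shares beyond 10 kb were at 9057755 to 9060313, with 1.16% ± 0.776 at CT6 and 1.976% ± 0.368 at CT18, and at 9054055 to 9057704, with 1.082% ± 0.681 and 1.459% ± 0.603. Next came the regions at 8985098 to 8993393, with 0.483% ± 0.453 and 2.049% ± 0.366, and 8996070 to 8997765, with 1.452% ± 0.382 and 1.003% ± 0.46. The annotation of these fragments was not used here, since the coordinates are in mm9. Of 178 regions tested by edgeR 0 were called between CT18 and CT6, with 26 at an unadjusted p under 0.05, and DESeq2 called 26, of which 22 were higher at CT18. The lowest p was that of the bait fragment (log2 -0.91, adjusted p = 0.27 by edgeR). Next in p came 9283566 to 9284306, at 0.154% ± 0.076 of the counts at CT18, and among the next few was 9164533 to 9165202, at 0.287% ± 0.235. Both had at most 5 counts in any library of CT6 (adjusted p = 0.27 by edgeR, called by DESeq2). Without CT6 replicate 1 edgeR called 9 regions, the bait fragment among them (adjusted p = 0.0371), without CT18 replicate 3 the bait fragment alone (0.00283) and without CT6 replicate 3 a distant region. Of 2610 fragments listed in any library, 204 were listed in all 6 and 1063 in 1. Beyond 1 Mb, 835 fragments had over 1000 counts in some library, of which 806 had them in exactly 1 library and 0 in 3 or more.

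**Figure D5:**
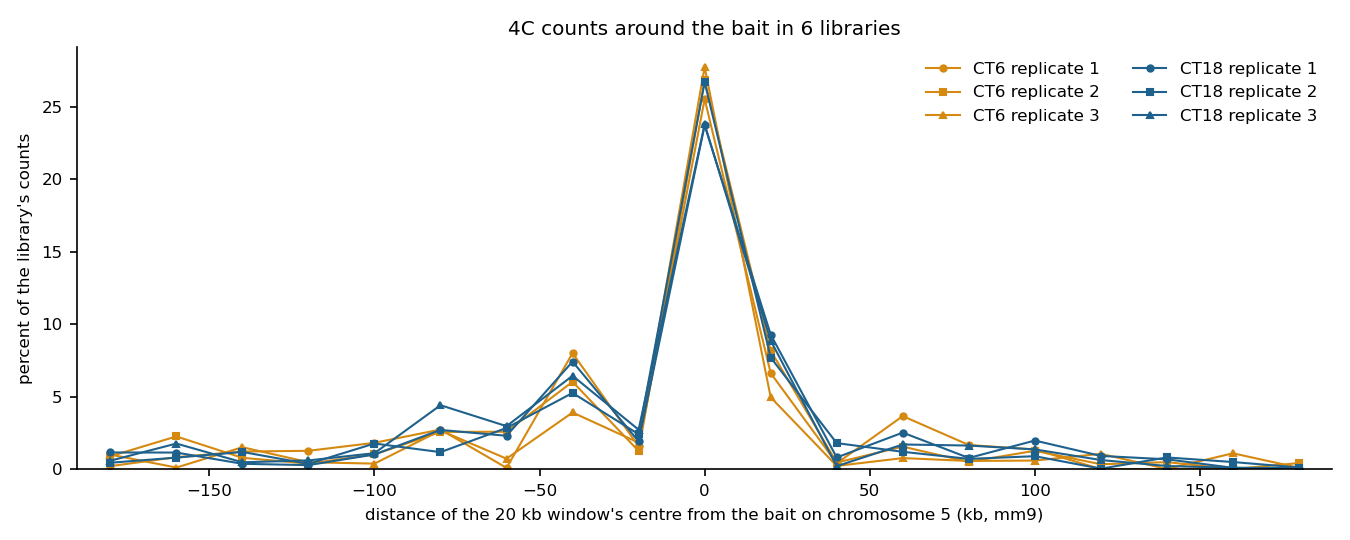
Percent of a library's chromosome 5 counts per 20 kb window (vertical) against distance from the bait in kb (horizontal) for the 3 libraries of CT6 and the 3 of CT18, each line being a library. The bait fragment alone held 14.535% of the counts at CT6 and 10.899% at CT18.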

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

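The interaction test and its alternatives were chosen before the data were examined, and the other splits of the livers were counted only after the result was seen. The change from CT0 to CT12 differed between control livers and livers labelled Bmal1 knockout in 150 genes by limma, which puts them here as effects that differ between groups. Positive interactions included those of Elovl3 (5.02), Cdkn1a (3.23), Tubb2a (2.93), Insig2 (2.88), Arntl (2.82), Spon2 (2.51), Clpx (2.40), Crot (2.20), Ppp1r3c (2.12), Npas2 (1.97), Hsd3b7 (1.43), the fibrinogen chains Fga (1.20) and Fgg (1.14), the lipopolysaccharide binding protein Lbp (1.04), Clock (1.03) and Abcb11 (0.81). Negative ones included those of Gm129 (-3.64), Per3 (-2.67), Dbp (-2.62), Cyp2a5 (-2.56), Cyp2a4 (-2.56), D0H4S114 (-2.35), Wee1 (-2.33), Upp2 (-2.16), Per2 (-2.13), Tef (-1.94), Gys2 (-1.83), Por (-1.49) and Abcb1a (-1.20). Reads of Cyp2a4 and Cyp2a5, and of Tubb2a and Tubb2b, may be shared.

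In 6 of 100 splits drawn, the real one included, the interaction gave 150 genes or more, and the highest of the others gave 237. By this count alone chance is not excluded for the number of genes. The 5 splits with the most genes kept the genotype labels at CT12 and exchanged 1 or 2 pairs of livers between genotypes at CT0, so they carry the difference at CT12, where 1107 genes were called, into the interaction. The count thus does not measure chance alone. In 91 of the splits drawn the genotypes were mixed at CT12, and the highest count among these was 1.

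Other splits of the livers were counted for the other Bmal1 comparisons as well. Knockout against control gave 185 genes at CT0 and 1107 at CT12, with a highest other count of 0 at each time. CT12 against CT0 gave 1239 genes in control livers (highest other 0) and 217 in knockout livers (highest other 4). For each of these 4 comparisons 1 of 10 splits, the real one, reached the real count, and 10 splits are too few for a share under 0.05.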

How the results depend on the processing

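The tests with the block together with edgeR, TMM factors, a left-out library or Ddx3y, and with 20 kb windows, were chosen only after the results were seen. Of the values of named genes under the alternatives, 3181 in the Bmal1 experiment kept direction and call, 418 kept the direction but lost the call, and 0 turned. Calls of named genes were lost without at least 1 library for 14 of 36 at CT0, 6 of 56 at CT12, 8 of 41 in control time, 19 of 25 in knockout time and 11 of 29 in the interaction. In the Nr1d1 experiment the comparison was with the fit without a block, which called 0 genes. There 612 values kept the direction and stayed uncalled, and 119 gained a call. The 4 that turned were all in fits without a block and with 1 library left out. Of 39 named values 32 were called with the block, 24 with TMM factors and the block, and 19 with Ddx3y and the block. Genes named from the blocked fits were chosen after their values were seen, so these counts follow in part from that choice. For the values below the cause was not tested, except that fewer libraries or groups in a fit leave fewer degrees of freedom. The Bmal1 counts at CT0 were 116 with no filter on RPKM and 108 with only the compared groups, and 25 over time in knockout livers with only these groups. With replicate number as a block the Bmal1 counts were 172, 1041, 1161, 180 and 121. Leaving out 1 library gave 82 to 184 at CT0, 713 to 901 at CT12, 633 to 1025 in control time, 48 to 232 in knockout time and 81 to 139 in the interaction. With a library left out the rank correlation of both knockouts lay between -0.024 and 0.136 at CT0 and between 0.13 and 0.294 at CT12, where the 4 lowest were those without a Nr1d1 library and with no block.

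In the Nr1d1 experiment the counts were 0 without a block. With the block they were 5 at CT12, 45 in control time and 7 in knockout time. The block with edgeR gave 1 at CT0, 10, 60 and 4, and 2 in the interaction. The block with TMM factors gave 1 at CT0, 2, 47 and 3, the block without the knockout CT0 library of replicate 2 gave 4, 37 and 1, and the block with Ddx3y gave 2, 48 and 1. Leaving out a library moved Nr1d1 itself between -0.60 and 4.09 at CT0 and between -0.89 and 2.21 at CT12, and Arntl over knockout time between -0.65 and 0.61 (0.59 without knockout CT12 replicate 1). In the fits where they turned, the median of all genes was -1.01, -0.80, 1.15 and 1.05, so these values hold the difference in RPKM scale between replicates. In the fits without a block, the lists called by camera over all contrasts fell from 51 to 3 in the Bmal1 experiment with an estimated correlation. In the Nr1d1 experiment they fell from 62 to 3. These counts do not cover the Nr1d1 list values given with the block.

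For 4C regions DESeq2 called 26, RLE factors 1 (the bait fragment) and 20 kb windows 1 (the window that holds the bait), and leaving out a library gave 0 to 9. The region at 9057755 to 9060313 turned to -0.60 with DESeq2 and with RLE factors and lay between -2.32 and 0.81 with a library left out. The region at 9054055 to 9057704 turned to -0.83 with both and lay between -2.31 and 0.34. The share of counts on the bait chromosome and its alternatives were not run, because the counts cover chromosome 5 only. What depth limits was not tested. In simulated 4C data edgeR recovered 0 of 40 changed regions at the dispersion of the real libraries and 18 at 0.1 of it.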

Other observations

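Of 24 acute phase genes, which encode plasma proteins of inflammation, 6 fell in control livers of the Bmal1 experiment from CT0 to CT12 (10 fell and 1 rose adjusted over the list alone; camera downward, adjusted p = 0.0061; adjusted p = 0.581 with an estimated correlation), including Fga (-0.81), Fgg (-0.87), Apcs (-0.94) and Lbp (-0.67). In livers labelled Bmal1 knockout 6 were higher than in controls at CT12 and 1 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.299). These included Apcs (1.43), Itih3 (1.09), Lbp (0.95), Fgg (0.91) and Fga (0.87). Saa4, a constitutive serum amyloid A gene, fell at CT0 (-1.63) and at CT12 (-1.26). At CT0 camera called the list downward with 1 gene called (adjusted p = 0.000237; adjusted p = 0.404 with an estimated correlation). Heat shock genes split in controls over time, 3 of 22 rising and 2 falling (6 and 2 adjusted over the list alone; camera adjusted p = 0.0167; adjusted p = 0.581 with an estimated correlation), and Hspb1 was lower in knockout livers at CT12 (-1.43). Immediate-early genes had 0 calls by limma between genotypes at either time (camera downward at CT0, adjusted p = 0.00322; adjusted p = 0.185 with an estimated correlation). The cell cycle list had 1 rise at CT0, the cyclin gene Ccne2 (1.21), with a camera adjusted p of 0.00537 and an adjusted p = 0.404 with an estimated correlation.

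Among other cell types, the cholangiocyte genes Spp1 and Sox9 were higher in livers labelled Bmal1 knockout at CT12 (1.58 and 0.85), and Spp1 at CT0 (1.16). At CT12 and CT0, 2 and 1 of 4 cholangiocyte markers were called, over all genes and adjusted over the list alone (camera adjusted p = 0.133 and 0.0309; adjusted p = 0.869 and 0.63 with an estimated correlation). The hemoglobin genes Hba-a2 (1.21) and Hbb-b2 (1.24) rose at CT12, where reads of Hbb genes may be shared, and fell over time in controls (-0.96 and -1.01). Of 9 hepatocyte markers 1 rose and 1 fell at CT12, also when adjusted over the list alone. Leaving out 1 library ended, for at least 1 choice of the library, the calls of Ccne2 and Spp1 at CT0, of Hspb1, Hba-a2 and Hbb-b2 at CT12, and of Fga, Apcs, Lbp, Hba-a2 and Hbb-b2 over time in controls. Kupffer cell, endothelial, stellate and lymphocyte markers had 0 calls by limma between genotypes at either time in the Bmal1 experiment (camera adjusted p = 0.479 for Kupffer cell markers and 0.993 for the others at CT12). Of the pancreatic acinar markers 2 of 11 passed the filter in both experiments, and of the adipocyte markers 1 of 6 in the Bmal1 experiment, too few for a test. The 3 adipocyte markers of the Nr1d1 experiment had 0 calls with the block (camera adjusted p = 0.566 at CT0 and 0.72 at CT12).

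The tests of explanations below were all chosen after the results were seen. Sex-biased liver genes changed between CT0 and CT12 in replicate 1 of the Nr1d1 experiment. Time of day alone is argued against by the female-biased median of -0.41 in controls of replicate 2, against 5.54 in replicate 1. Bmal1 control livers, which express Y-linked genes, had medians of 1.17, -0.46 and 0.72 over 12 such genes, below the lowest gene of replicate 1 (2.12). A candidate explanation is that the livers of replicate 1 came from males at CT0 and females at CT12, since the Y-linked medians there were -3.05 in control and -2.98 in knockout livers, while the X-linked copies were higher (0.77 and 0.90). In replicate 2 the knockout CT0 library was apart. A male liver among female livers is argued against by the Y-linked genes, all 4 of which were at 0 RPKM in it, against 1.585 to 9.897 in the knockout CT0 library of replicate 1. The X-linked copies mostly went the other way, as a male liver would have it. Ddx3x (45.88 against 73.06 RPKM), Kdm6a (4.011 against 5.636) and Eif2s3x (82.85 against 138.5) were lower than in the control CT0 library of replicate 2. Kdm5c was higher (63.58 against 50.92). Y-linked reads could be listed in replicate 2, where Kdm5d stood at 0.1462 in the knockout CT12 library. Loss of Nr1d1 stays open as its cause. The female-biased median between genotypes at CT0 was 0.24 in replicate 1, but these genes were already low in its CT0 livers, and at CT12 the medians were -2.41 and -0.34. Neutrophil, erythroid and acute phase genes were higher in that library as well, so other differences between the livers stay open too.

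Among the genes called at CT12 in the Bmal1 experiment, 66.8% were higher in knockout livers, and 48.3% with TMM factors. Albumin took a smaller share of RPKM in knockout livers, which raises all other genes. With albumin left out of the sum 59.1% of the called genes were still higher, against 68.6% with it. The values with a library left out had an SD of 4.285 in the deposited scaling. They share most of their libraries, so this SD understates the error, and albumin as the whole cause is not excluded. A general rise of expression may also contribute. In 10 groups of genes of equal size by mean expression the medians were 0.055 to 0.120, but RPKM has no absolute scale, so a general rise and a change in composition cannot be told apart here.

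In the 4C libraries 212 fragments beyond 1 Mb had over 1000 counts in CT18 replicate 1, and CT18 replicate 2 listed all 212. At 201 of them every other library had at most 5% of the count of CT18 replicate 1, and CT18 replicate 2 had a median of 39 counts. Contacts shared by livers at CT18 are argued against, since CT18 replicate 3 listed 37.3% of the 201 (39.6% of the 212). A candidate explanation is that reads were carried from one library to the other: the counts of both libraries correlated across fragments (Spearman 0.96), at 12.957 per 1000 counts of the donor, against 0.38 and 0.164 in CT18 replicate 3. Other pairs were close as well. At fragments chosen in the same way in CT18 replicate 2, CT18 replicate 1 listed 94.7% (Spearman 0.79), and CT6 replicates 2 and 3 listed 87.0% and 87.1% of each other's (0.68 and 0.69). The remaining pairs listed 24.8% to 62.3%. By edgeR the real count of regions was 0, which each of the 10 splits of the 6 libraries reaches by definition, so these splits decide nothing (highest other 3). By DESeq2 3 of 10 splits gave as many regions as the real one (real 26, highest other 29), and 10 splits are too few for a share under 0.05.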
